A study of Homo sapiens with 6 samples.

How the data were processed

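Small RNA sequencing was carried out on exosomes of MDA-MB-231 cells, an established human triple-negative breast carcinoma line. Stable clones carried either a control hairpin (shNC) or a hairpin against MCU (shMCU), the gene for the pore-forming subunit of the mitochondrial calcium uniporter. Per the labels' protocols, cells were grown in medium with exosome-free serum, and exosomes were enriched with polyethylene glycol and ultracentrifugation. RNA was isolated with a column kit and libraries were made with an adapter-ligation kit for small RNA. There were 3 libraries per group, 6 in all, assigned from the sample titles. Nothing in the labels says that the replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

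The deposited values are whole-number read counts per mature miRNA, 1 table per library, not normalized by the authors. Their unit was read from the values, which are whole and sum to a different total in each library. Per the submitters' processing notes, reads were aligned with Bowtie to hg19. The Bowtie version, the mismatch setting, the treatment of reads that match several miRNAs, the counting tool and the miRNA annotation release are not given in the sources used here. Each table listed the same 503 mature miRNAs, and 490 of them (97.4%) were matched by name to hairpin genes of GENCODE release 29. That annotation is on GRCh38, not on the build of the alignment; the coordinates given are those of GRCh38, and no coordinates were converted. The kit is not stated to add molecular identifiers, so PCR copies are not told apart from separate molecules, and the intervals on counts cover counting error only. Family members that differ by a base, such as those of let-7, and miRNAs with several hairpin copies can share reads, and their separate counts are uncertain.

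Totals were low, from 11563 to 47863 counts per library. A count of 3, the limit that a count of 0 allows, corresponds to 62.7 CPM (counts scaled to a common library total) in the deepest library and 259 CPM in the shallowest. Of the listed miRNAs, 79 passed edgeR's filter on low counts (filterByExpr with its minimum count of 10), and they held between 95.5% and 96.6% of each library's counts.

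Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust fit, TMM normalization, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F, and 95% intervals from the matching t quantile. Printed CPM and percentages use the sum over all listed miRNAs as the denominator and are not TMM-scaled, while the fold changes are. TMM factors ran from 0.818 in shMCU replicate 3 to 1.12 in shNC replicate 1, so the direction can differ. For example, miR-7704 had a mean of 7358 CPM in shNC and 6918 CPM in shMCU but a fitted fold of 1.15. Lists of miRNAs were tested with camera of limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2, for lists with at least 3 tested members; camera with an estimated correlation and fry were run beside it. The shares and detection counts were compared with two-sided exact permutation tests over the 20 arrangements of the libraries, for which the smallest p is 0.1.

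Before the data were examined, 18 lists of miRNAs were fixed from background knowledge: families and clusters, miRNAs linked to metastasis, angiogenesis, mitochondria or exosome sorting, markers of other cell types, and annotated miRNAs whose reads have been ascribed to other RNAs. The miRNAs named in the text follow a rule fixed at the same time. It takes up to 10 miRNAs per direction past the threshold; where fewer than 5 pass, those with the smallest p fill up to 5 per direction and are stated as not passing. It adds the 10 most abundant miRNAs, up to 2 members of each list by mean and up to 2 by p, and miR-4488, a miRNA that published work on this system describes. The rule gave 45 miRNAs, of which 37 were tested. A further list of liver miRNAs was written later for the closing section.

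The alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, library totals alone, no filter, a filter of 100 counts in 3 libraries, the replicate number as a block, removal of the 10 most abundant miRNAs, each library left out in turn, and, chosen after seeing the data, limma voom with library quality weights and detection at equal depth. Alternatives planned for normalized values were not needed, since the tables hold counts.

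The main test was tested on simulated data for the comparison of shMCU with shNC: counts were drawn for the 79 miRNAs from the observed means, dispersions and library sizes, with 20 changed in each of 50 simulations. It recovered 32.8% of 2-fold, 92.0% of 4-fold and 98.4% of 8-fold changes and called 1.53% of unchanged miRNAs. In these simulations miRNAs varied independently of each other, which real libraries need not do. With 20 of 79 miRNAs changed, the adjusted threshold is also easier to pass than where few miRNAs change. No simulated library was made to stand apart, as shMCU replicate 3 did. The recovery rates therefore do not carry over to an isolated change in the real libraries. A simulated list of 6 miRNAs shifted 2-fold had an unadjusted camera p under 0.05 in 100% of simulations and an unshifted one in 2% of them. The real lists were held to an adjusted p over 11 lists, so the 100% does not carry over to them.

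A chi-square test of the counts was used only to look for repeat deposits of one library, and found no pair of libraries within counting noise (chi-square per degree of freedom from 4.08 to 53.9). It does not tell separate cultures from repeat preparations of one culture; the libraries were taken as separate samples from the labels.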

Results

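The series asks whether lowering MCU changes the miRNA content of exosomes that MDA-MB-231 cells release. Counts of mature miRNAs were available for 3 shNC and 3 shMCU exosome libraries. The total was 47863, 11563 and 19884 counts in shNC replicates 1, 2 and 3, and 12930, 14692 and 12859 counts in shMCU replicates 1, 2 and 3. Small RNA libraries do not measure the MCU transcript, so the knockdown itself could not be checked in these data. Across the 79 miRNAs tested, which are not independent replicates, the highest correlation of log2 CPM between any pair of libraries was that of shNC replicate 1 with shMCU replicate 1 (Pearson's r = 0.97), and the lowest that of shNC replicate 1 with shMCU replicate 3 (r = 0.87). The library of shMCU replicate 3 stood apart on the first principal component, which held 43.1% of the variance, with a score of 6.11 against -2.73 to 1.11 in the other 5 libraries.

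In both groups a few miRNAs made up most of the exosomal counts. The most abundant was miR-21-5p, an oncogenic miRNA abundant in many carcinomas, with 21.0% ± 1.32 (SD, n = 3) of counts in shNC and 17.1% ± 5.15 in shMCU libraries. It was followed by miR-100-5p, with 11.5% ± 3.49 in shNC and 13.5% ± 1.26 in shMCU, and by miR-148a-3p, with 5.36% ± 1.22 and 9.34% ± 6.02. The let-7 family, a group of tumour-suppressive miRNAs, contributed let-7i-5p, let-7g-5p, let-7f-5p and let-7a-5p to the 10 most abundant. Of the remaining abundant miRNAs, miR-122-5p, the dominant miRNA of liver, held 1.78% ± 0.551 in shNC and 5.48% ± 4.28 in shMCU libraries. For the libraries as a whole, whether these miR-122-5p reads came from the cells or from the serum of the medium was not tested. Shares of miR-92a-3p, from the oncogenic miR-17-92 cluster, were 3.87% ± 1.46 and 3.12% ± 1.33, and those of miR-27b-3p 3.47% ± 0.0878 and 2.36% ± 0.394. Together the 10 most abundant miRNAs took 66.5% ± 2.51 of counts in shNC and 69.8% ± 2.92 in shMCU libraries, a difference within the spread of the libraries (exact permutation test, two-sided p = 0.30, unadjusted). On GRCh38, the hairpin of miR-21 (MIR21) lies on the plus strand of chromosome 17 from 59841266 to 59841337, within an exon of VMP1. MIR100 lies on the minus strand of chromosome 11 from 122152229 to 122152308, in an intron of MIR100HG, and MIR148A on the minus strand of chromosome 7 from 25949919 to 25949986, with no host gene on that strand.

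**Figure D1:**
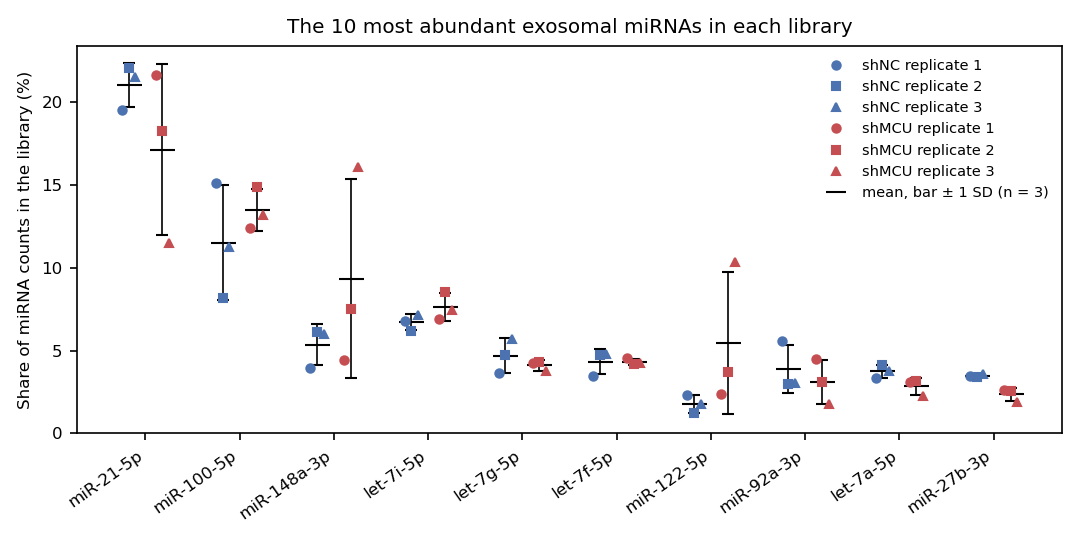
Share of each library's miRNA counts (%, linear axis) taken by the 10 most abundant miRNAs, with 1 point per library, the group mean as a dash and a bar of 1 SD either side (n = 3). The shMCU replicate 3 library departs from the other libraries, with 16.1% miR-148a-3p, 10.4% miR-122-5p and 11.5% miR-21-5p.

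No miRNA differed between shMCU and shNC exosomes after adjustment. Of 79 miRNAs tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, the smallest adjusted p being 0.70, and 3 had an unadjusted p under 0.05 where chance gives 3.95. DESeq2 on the same miRNAs called 1, miR-122-5p, and limma voom with library quality weights called 0, with 6 at an unadjusted p under 0.05. Fitted fold changes were higher in shMCU for 38 miRNAs and lower for 41; with library totals in place of TMM, 24 were higher and 55 lower, as the median log2 fold change of all tested miRNAs went from -0.02 to -0.24. The 95% interval of a fold change spanned a factor of 1.74 either side at the median. For a typical miRNA at this spread between libraries, a smaller fitted change does not reach an unadjusted p of 0.05. The adjusted test needs a larger change than that, so 1.74 is not its limit of detection.

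The largest fitted difference was that of miR-122-5p, at 17793 ± 5508 CPM (SD, n = 3) in shNC and 54828 ± 42839 CPM in shMCU libraries, the only tested miRNA for which every shMCU library lay above every shNC library. Its log2 fold change was 1.93 ± 0.63 (SE), a fold of 3.80 with a 95% interval from 1.35 to 10.7, and its adjusted p was 0.70 by edgeR's quasi-likelihood test (unadjusted p = 0.018). DESeq2 gave the same size, a log2 fold change of 1.95, with an adjusted p of 0.0105. The value rested largely on shMCU replicate 3: CPM were 23589, 37231 and 103663 in shMCU replicates 1, 2 and 3, and the log2 fold change was 0.85 without replicate 3. The separation of the groups was narrow, with shMCU replicate 1 at 23589 CPM and shNC replicate 1 at 23296 CPM. The hairpin gene MIR122 lies on the plus strand of chromosome 18 from 58451074 to 58451158 (GRCh38), within an exon of MIR122HG. Second by p was miR-151a-3p, from an intron of PTK2 on chromosome 8 (MIR151A, 140732564 to 140732653, minus strand), with 11143 ± 603 CPM in shNC, 19007 ± 9250 CPM in shMCU and a fold of 2.06 (95% interval 1.07 to 3.97). Its log2 fold change went from 1.05 to 0.47 without shMCU replicate 3. The same library held the highest miR-148a-3p share, and the fitted fold of miR-148a-3p, 2.13 (0.88 to 5.16), became a log2 fold change of 0.28 from 1.09 without it.

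The other miRNAs with the smallest p on the higher side had smaller folds. They were miR-4461 with a fold of 1.56 (95% interval 1.00 to 2.42), miR-7641 with 1.66 (0.94 to 2.96) and miR-10a-5p, a HOX-cluster miRNA, with 1.40 (0.95 to 2.07). The hairpin annotated as MIR4461, in an intron of PCBD2 on chromosome 5 (134928039 to 134928112), shares at least 18 bases with a mitochondrial transcript, and those of miR-7641 share as many with annotated ribosomal RNA. Whole hairpins were searched, on either strand for mitochondrial transcripts, so the shared bases may lie outside the mature miRNA or be antisense. Whether reads of those RNAs were counted as these miRNAs was not tested. On the lower side, miR-181b-5p had 2713 ± 439 CPM in shNC and 1594 ± 496 CPM in shMCU, a fold of 0.67 (0.42 to 1.06). Its family member miR-181a-5p had a fold of 0.79 (0.53 to 1.18). miR-320b had a fold of 0.65 (0.37 to 1.14), miR-27b-3p 0.78 (0.56 to 1.09), miR-17-5p 0.58 (0.27 to 1.25) and miR-93-5p 0.65 (0.34 to 1.23). None of these passed the adjusted test (adjusted p = 0.70 for each except miR-181a-5p, at 0.71, edgeR's quasi-likelihood test). By CPM, all 3 shMCU libraries lay below all 3 shNC libraries for 8 of the 79 miRNAs, including let-7a-5p and miR-27b-3p, and above them for 1, together 11.4% where chance gives 10%. These CPM are not TMM-scaled, and with library totals alone 24 of the 79 were fitted higher and 55 lower.

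**Figure D2:**
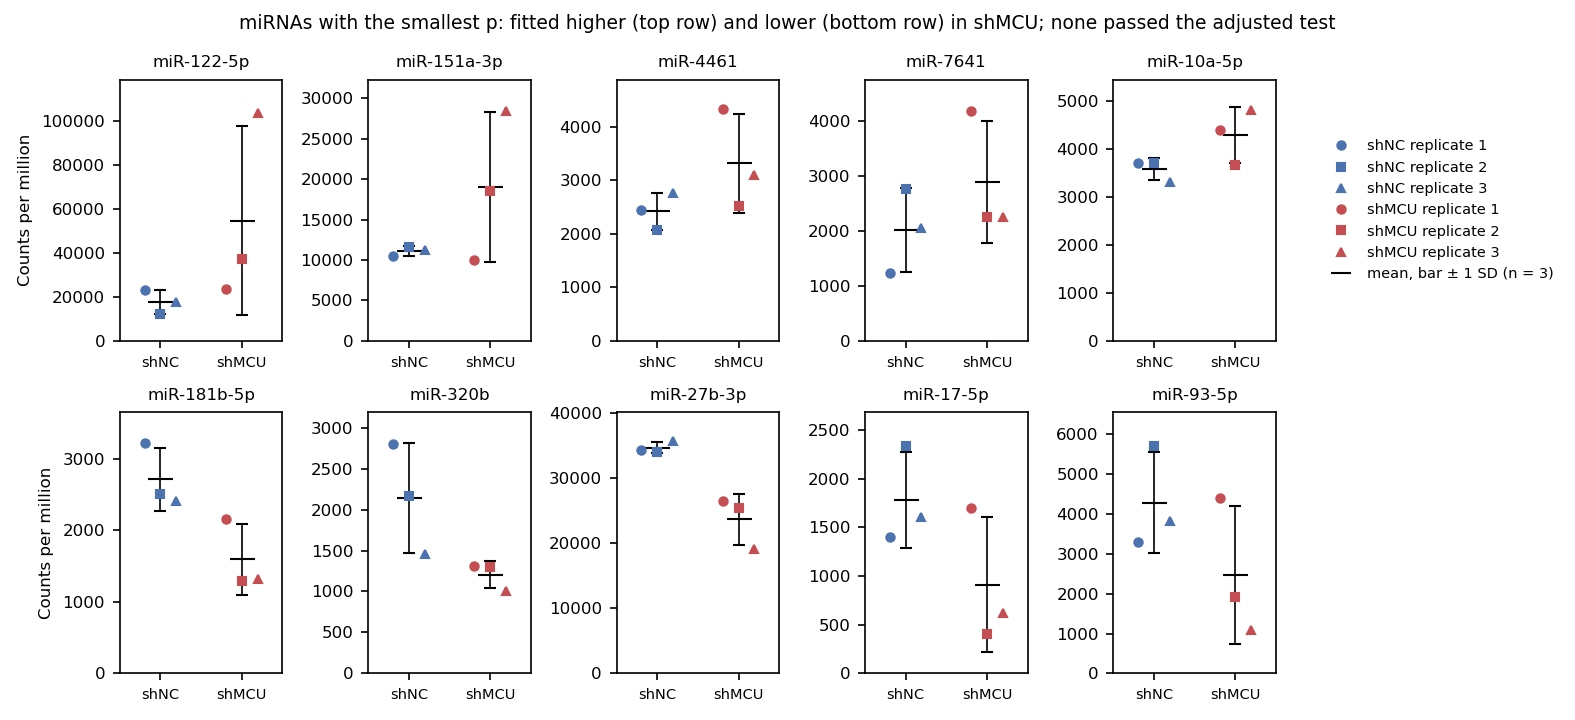
CPM (linear axes from 0) of the 5 miRNAs with the smallest p among those fitted higher in shMCU (top) and the 5 fitted lower (bottom), with 1 point per library and the group mean ± 1 SD (n = 3). In shMCU replicate 3, miR-122-5p reached 103663 CPM, while the other shMCU libraries were at 23589 and 37231 CPM.

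Lists of miRNAs were compared to see whether families, clusters or functional groups moved together. Of 11 lists with at least 3 tested members, 0 passed an adjusted p of 0.05 by camera, by camera with an estimated correlation or by fry. The lowest camera p belonged to the oncogenic miR-17/92 clusters. Of their 5 tested members, 4 were fitted lower and 1, miR-25-3p, fitted higher (lower with library totals alone), with a median log2 fold change of -0.54 (unadjusted p = 0.032, adjusted p = 0.32 by camera; unadjusted p = 0.14 with an estimated correlation). That median was -0.14 without shMCU replicate 3 and -1.02 without shMCU replicate 1 (adjusted p = 0.48 and 0.064 by camera). Their joint share was 6.63% ± 1.62 (SD, n = 3) in shNC and 5.24% ± 1.84 in shMCU libraries, lowest in shMCU replicate 3 at 3.34%. All 5 members of the miR-23/27/24 clusters were fitted lower, with a median of -0.20 (adjusted p = 0.32 by camera), among them miR-24-3p at a fold of 0.87 and miR-23a-3p at 0.85. Each of the 3 tested members was also fitted lower (2 of 3 in each family without the 10 most abundant miRNAs) in the miR-320 family (median -0.48, adjusted p = 0.39 by camera), where miR-320a had a fold of 1.00 and miR-320c of 0.72, and in the miR-30 family (median -0.25, adjusted p = 0.76 by camera). There, the folds of miR-30a-5p, miR-30d-5p and miR-30e-5p were 0.84, 0.97 and 0.74. Without shNC replicate 2 all 3 were fitted higher, with log2 fold changes of 0.11, 0.21 and 0.064. The let-7 family held 20.8% ± 1.93 of counts in shNC and 20.04% ± 1.39 in shMCU libraries, with 5 of 8 tested members fitted higher, or 2 of 8 with library totals alone (median 0.03, adjusted p = 0.83 by camera).

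None of the functional lists passed either. Among miRNAs reported to promote metastasis, which include miR-122-5p, 3 of 7 tested were fitted higher, and the median (-0.06) and the mean log2 fold change (0.29) differed in sign. Camera's direction was up (adjusted p = 0.83). Another member, miR-183-5p, had a fold of 1.58 (0.93 to 2.69). Of those reported to suppress metastasis, 3 of 5 were fitted higher (median 0.03, adjusted p = 0.83 by camera), including miR-7-5p at a fold of 1.24; their joint share was 7.25% ± 1.61 in shNC and 11.2% ± 5.86 in shMCU, most of it miR-148a-3p. In shMCU replicates 1, 2 and 3 that share was 6.54%, 9.35% and 17.8%, the last from the library that stood apart. The angiogenesis-linked list had 2 of 7 tested members fitted higher (median -0.11, adjusted p = 0.83 by camera), with miR-100-5p at a fold of 1.37 (0.90 to 2.08). Mitochondria-linked miRNAs, which include miR-25-3p (fold 1.09), known to target MCU, and miR-378a-3p (fold 1.28), had a median of 0.12 and a mean of -0.06. Their direction was up by camera and down by fry (adjusted p = 0.83 and 0.98). The list reported as exosome-sorted had 3 of 4 fitted lower (median -0.24, adjusted p = 0.57 by camera), and 4 of 6 annotations resembling other RNAs were fitted higher (median 0.14, adjusted p = 0.77 by camera), among them miR-1246 at a fold of 1.06, miR-7704 at 1.15 and miR-3648 at 1.47. With library totals alone, the medians of the metastasis-suppressing, mitochondria-linked and RNA-resembling lists were below 0, at -0.19, -0.11 and -0.11. Adjusted over the list alone, 0 members passed in every list except the blood cell and liver list, whose only tested member was miR-122-5p.

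**Figure D3:**
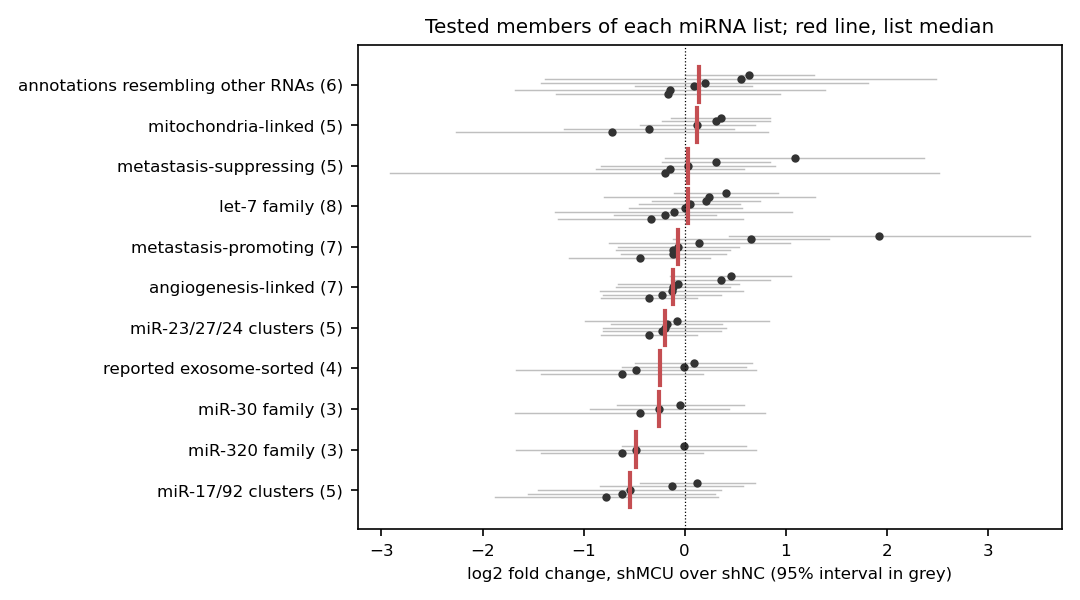
Log2 fold change of shMCU over shNC (linear axis) for each tested member of the 11 lists, with its 95% interval in grey and the list median in red; the number of tested members stands beside each list. The lists' medians lie between -0.54 and 0.14, and the interval of miR-122-5p, in the metastasis-promoting list, is the only one on a single side of 0 apart from that of miR-4461.

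The remaining 7 lists had fewer than 3 tested members. The miR-181 family held 0.591% ± 0.0497 (SD, n = 3) of counts in shNC and 0.380% ± 0.0797 in shMCU libraries. In the miR-15/16 family, miR-16-5p had a fold of 0.78 (0.44 to 1.40) and miR-503-5p of 1.83 (0.76 to 4.38). In the miR-29 family, miR-29a-3p had a fold of 0.89 (0.58 to 1.38), and miR-29b-3p, under the filter, had 10, 4 and 8 counts in shNC and 2, 0 and 2 in shMCU replicates 1, 2 and 3. Epithelial miRNAs of the miR-200 family and miR-205 were scarce, as were miRNAs of the imprinted cluster on chromosome 14q32. They took 0.107% ± 0.0892 and 0.218% ± 0.0676 of counts in shNC and 0.0734% ± 0.0463 and 0.178% ± 0.0315 in shMCU, led by miR-205-5p and miR-200c-3p, and by miR-127-3p and miR-381-3p. Among blood cell markers, miR-486-5p had 314 ± 127 CPM in shNC and 482 ± 253 CPM in shMCU. Muscle and neural miRNAs took 0.257% ± 0.114 and 0.286% ± 0.106; their most abundant members were miR-128-3p, with a fold of 1.12 (0.58 to 2.18), and miR-9-5p, with 264 ± 296 CPM in shNC and 689 ± 608 CPM in shMCU.

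For miR-4488, a GC-rich miRNA from chromosome 11 (MIR4488, 61508596 to 61508657 on GRCh38, plus strand, with no host gene on that strand), few reads were counted. There were 2, 0 and 3 counts in shNC and 0, 5 and 6 counts in shMCU replicates 1, 2 and 3. Summed over each group, 5 of 79310 and 11 of 40481 counts gave a ratio of 4.31 in favour of shMCU, with an exact 95% interval from 1.38 to 15.8 that covers counting error only. Single libraries moved that ratio from 2.85 without shNC replicate 1 to 8.07 without shNC replicate 3; it was 2.87 without shMCU replicate 3 and 6.33 without shMCU replicate 1. The miRNA was below the filter of the main test; without that filter its log2 fold change was 1.98 ± 0.86 (SE), with an adjusted p of 0.68 by edgeR's quasi-likelihood test and an unadjusted p of 0.022. The 0 counts in shMCU replicate 1 allow up to 232 CPM, so a difference in that library was not detectable at this depth.

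The number of miRNAs with at least 1 count was 303 ± 58.8 (SD, n = 3) in shNC and 253 ± 6.35 in shMCU libraries (exact permutation test, two-sided p = 0.30, unadjusted). It was highest, at 368, in the deepest library, shNC replicate 1; the difference of -50 (shMCU minus shNC) was -17.7 without that library and -75.2 without shNC replicate 2. With at least 10 counts, there were 102 ± 27.2 miRNAs in shNC and 76.0 ± 3.61 in shMCU libraries, with each shMCU library below each shNC library (exact permutation test, two-sided p = 0.1, the smallest that this design allows). At an equal depth of 11563 counts, the expected number was 245 ± 7.89 in shNC and 241 ± 6.39 in shMCU libraries (exact permutation test, two-sided p = 0.60). With at least 10 counts at that depth, it was 76.0 ± 4.43 in shNC and 71.5 ± 3.39 in shMCU libraries, and the groups overlapped (exact permutation test, two-sided p = 0.30).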

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

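The quality-weighted fit and the detection at equal depth, with at least 1 or 10 counts, were chosen after seeing the data; the other alternatives were planned. The count of miRNAs past an adjusted p of 0.05 was 0 in the edgeR test and stayed 0 with DESeq2 size factors, library totals alone, the stricter filter, removal of the 10 most abundant miRNAs, quality weights and each library left out in turn. DESeq2 called 1 (miR-122-5p, log2 fold change 1.95) and the test without a filter called 1 (miR-375, with 15 of its 17 counts in shMCU replicate 2; it lies outside the naming rule and was chosen after its values were seen). For the miR-122-5p call the cause was not tested. Adjusted p of miR-122-5p ranged from 0.0105 to 0.99 over the alternatives. The number at an unadjusted p under 0.05, 3 in the main test, was 10 without a filter, 6 with quality weights and 1 to 12 with a library left out: 12 without shMCU replicate 1, and 1 without shMCU replicate 3, shNC replicate 2 or shNC replicate 3. No pairing by replicate number was seen. Deviations from the group means of same-numbered libraries correlated at 0.16, -0.35 and 0.08, and not every library correlated best with its own number. With 3 libraries per group these deviations depend on each other, so the check cannot exclude that equal numbers share a batch. A replicate block gave 0 calls, 3 miRNAs at an unadjusted p under 0.05 and a log2 fold change of 1.61 for miR-122-5p, and changed no call. List tests called 0 lists in every alternative run. The share of the 10 most abundant miRNAs differed by 3.30 percentage points, while that of the most abundant miRNA alone differed by -3.90 points (shMCU minus shNC); that miRNA is miR-21-5p. Leaving out libraries moved the first to between 1.91 and 4.85 points, and the difference in detected miRNAs, -50, to between -75.2 and -17.7. Of 490 fold changes of named miRNAs under the alternatives, 452 kept their sign and side of the threshold, and the 37 that changed sign belonged to 13 miRNAs, none of them called. With library totals alone these were let-7g-5p -0.20, let-7f-5p -0.0077, miR-25-3p -0.11, miR-128-3p -0.034, miR-7704 -0.066 and miR-1246 -0.14. Without a filter they were let-7g-5p -0.16, miR-25-3p -0.073, miR-128-3p -0.074 and miR-1246 -0.089, and with the stricter filter let-7g-5p -0.13 and miR-25-3p -0.039. With quality weights they were let-7g-5p -0.075, miR-92a-3p 0.018, miR-30d-5p 0.084 and miR-320a 0.038, and without the 10 most abundant miRNAs miR-30d-5p 0.046 and miR-320a 0.070. Leaving out libraries gave log2 fold changes of -0.24 to 0.0082 for miR-21-5p, -0.18 to 0.22 for let-7g-5p, -0.40 to 0.18 for miR-92a-3p, -0.076 to 0.29 for miR-25-3p, -0.49 to 0.11 for miR-30a-5p, -0.23 to 0.21 for miR-30d-5p, -0.97 to 0.064 for miR-30e-5p, -0.26 to 0.15 for miR-320a, -0.18 to 0.54 for miR-128-3p, -0.28 to 0.86 for miR-7704, -0.12 to 0.19 for miR-1246 and -0.084 to 1.09 for miR-3648. With a library left out, some list medians kept their sign, with ranges of -1.02 to -0.14 for the miR-17/92 clusters, -0.72 to -0.14 for miR-320, -0.38 to -0.072 for the miR-23/27/24 clusters and -0.44 to -0.097 for exosome-sorted miRNAs. Other list medians went from -0.039 to 0.13 for let-7, -0.49 to 0.11 for miR-30, -0.14 to 0.18 for metastasis-promoting, -0.11 to 0.38 for metastasis-suppressing, -0.33 to 0.015 for angiogenesis-linked, -0.076 to 0.24 for mitochondria-linked miRNAs and -0.16 to 0.32 for annotations resembling other RNAs. For these changes of sign the cause was not tested. Depth limits the comparison to abundant miRNAs: 79 of the 503 listed miRNAs passed the filter, and miR-4488 was counted 16 times in all libraries together.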

Other observations

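The tests of carry-over of serum or liver RNA, of depth and of reads from other RNAs were set before their results were seen; the splits of the libraries, the test of counting error and detection with at least 10 counts at equal depth were chosen after. Blood cell miRNAs were near the counting limit. Erythroid miR-451a had 7, 2 and 4 counts in shNC and 4, 3 and 3 counts in shMCU replicates 1, 2 and 3. The lymphoid and myeloid miRNAs miR-150-5p and miR-223-3p had at most 1 count in any library. Among liver and gut miRNAs, miR-192-5p had 86, 15 and 25 counts in shNC and 17, 20 and 23 counts in shMCU replicates 1, 2 and 3. The endocrine and luminal miRNA miR-375 was counted 15 times in shMCU replicate 2 and at most once in each other library. In miR-203a, an epithelial miRNA, single libraries of both groups stood out: it was at 4497 CPM in shNC replicate 2 and 2644 CPM in shMCU replicate 3, and between 68.1 and 1237 CPM in the other libraries. miR-186-5p was at 467 CPM in shMCU replicate 3 and between 2166 and 3370 CPM in the other libraries. miR-375, miR-203a and miR-186-5p were chosen after their values were seen.

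With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 0 adjusted calls, a count that any split reaches, and the highest other split gave 1. At an unadjusted p under 0.05 the real split gave 3 miRNAs and the highest other split 11, and 6 of 10 splits gave as many, the real one included.

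The clearest single feature was the share of miR-122-5p in shMCU replicate 3, at 4.50 times its CPM in the other 5 libraries (exact 95% interval 4.21 to 4.81). Counting error of reads alone does not account for it, since the ratio to the next highest library, shMCU replicate 2, was 2.78 (2.52 to 3.08). That interval takes each read as a separate molecule, and the miRNA and library were picked as extreme, so chance sampling of a few molecules is not excluded. Carry-over of blood or liver RNA cannot be told apart from the other explanations. The other blood cell miRNAs were at 1.53 times (0.80 to 2.73) and other liver miRNAs at 1.097 times (0.68 to 1.68), both below miR-122-5p, which had been set as the sign against carry-over; that bound was too strict, since the former ratio rests on 14 counts, with no marker above 9, and the latter on miR-192-5p, which has a level of its own in all libraries. By their labels all 3 shMCU libraries share the MCU knockdown, so it alone does not set replicate 3 apart from replicates 1 and 2. Its strength in each library was not measured, so a part for it was not tested. Amplification of a few molecules and differences between exosome preparations stay open, since other miRNAs departed in shMCU replicate 3 in both directions. There, miR-148a-3p was at 3.14 times, miR-203a at 2.57, miR-151a-3p at 2.41, miR-21-5p at 0.568, miR-20a-5p at 0.232, miR-4485 at 0.213 and miR-186-5p at 0.181 times.

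Fewer miRNAs were detected in shMCU than in shNC libraries, by 50 on average. At equal depth the difference was -3.97 (shMCU minus shNC), as a difference in library depth predicts. With at least 10 counts, each shMCU library was below each shNC library at full depth (a difference of -26.3), and at equal depth the difference was -4.53, with the groups overlapping. Most of the gap at full depth may therefore be technical, while a smaller effect of MCU knockdown on the number of miRNAs stays open.

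One hypothesis was that miR-4461 and miR-7641 have small p because fragments of mitochondrial or ribosomal RNA are more abundant in shMCU exosomes. Of the listed miRNAs, 5 have hairpins sharing at least 18 bases with mitochondrial transcripts on either strand. Their summed CPM was 3799 ± 331 (SD, n = 3) in shNC and 4422 ± 1337 in shMCU, a difference of 623 (exact permutation test, two-sided p = 0.70). For the 3 sharing bases with annotated ribosomal RNA, mitochondrial ribosomal RNA included, the difference was 605 CPM (exact permutation test, two-sided p = 0.60). Of these 3, miR-1973 and miR-4485 also belong to the mitochondrial set, so the tests of the sources are not separate. Both sets overlapped between groups, which had been set as the sign against the hypothesis; since miR-4461 itself also overlaps between groups and the standard errors of the differences were 795 and 1059 CPM, that bound was too strict and neither source can be excluded. Without miR-4461 the mitochondrial set was at 1370 ± 123.2 CPM in shNC and 1102 ± 639 CPM in shMCU libraries. Without miR-7641 the ribosomal set, then only miR-1973 and miR-4485, was at 1149 ± 132 CPM in shNC and 882 ± 592 CPM in shMCU libraries. The only ribosomal member outside the mitochondrial set was thus miR-7641 itself, the miRNA to be explained. The ribosomal test therefore held no separate measure of ribosomal RNA from outside mitochondria. The hypothesis remains open.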
